A study of Mus musculus with 12 samples.

How the data were processed

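Binding of the bromodomain proteins BRD2 and BRD3 was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in RAW264.7 cells, a mouse monocyte and macrophage line that can form osteoclasts. Per the labels' protocols, cells were left untreated or kept for 4 h with RANKL (50 ng/ml), with the bromodomain inhibitor I-BET (500 nM), or with both, and were fixed for 15 min in 1% formaldehyde. Single-end reads of 50 bp were sequenced. The series lists 12 libraries here, 1 per antibody and treatment for BRD2 and for BRD3 and 1 input library per treatment. The 4 inputs have no peak list and entered no comparison.

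The processed data were 8 peak lists, 1 for each antibody and treatment. FastQC, Bowtie2 2.3.4.1, MACS2 2.1.1.20160309 and the mm10/GRCm38 build are named in the submitters' processing notes, without settings. Each line of the deposited lists gives a chromosome, a start, an end, the names of the peaks joined into the region and a score. Per the peak names in the deposited files, nearly every region joins 1 peak from each of 3 peak sets, numbered 3, 5 and 7, so a region present in fewer sets is rare in the lists; the share of regions with exactly 3 joined peaks was 98.4% to 99.96%. What the set numbers stand for is not given in the sources used here. The score of a region in the deposited lists is the authors' own value and behaves as the mean over the joined peaks. For 98.9% to 99.96% of regions, 3 times the score lay within 1e-06 of a whole number. The score was used to rank, filter and group regions within a list. Scores were also correlated between neighbouring regions and between matched regions of different lists. Positions are those of the deposited lists, given here counted from 1. The lists give neither read counts nor depth, no signal height and no fold enrichment, so the depth of each library is unknown and only the presence, position, width and score of a region could be compared.

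Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the build of the peak lists. The table gives the start and end of each gene record but neither strand, exons nor transcript starts, so the promoter, exon and intron classes planned at first could not be used. In their place, a region was put at a gene end when its midpoint lay within 1 kb of either end of a protein-coding gene on chromosomes 1 to 19, X and Y, in a gene body when it lay elsewhere in such a gene, and otherwise between genes. A gene was counted as bound when a region overlapped by at least 1 bp the window within 1 kb of either of its ends. Such a window holds the 3' end of a gene as well as its promoter, and a region between neighbouring genes counts for both. A gene counted in both of a pair of lists can thus have its regions at different places. In all 21887 genes were used.

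Regions of different lists were called shared when they overlapped by at least 1 bp. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Observed overlaps were set beside 100 random placements of the same intervals on the same chromosome. The number of members of a gene list with a peak was ranked among 10000 random lists of protein-coding genes matched on the length of the window. For a pair of lists, the number of members called in the first and not the second was ranked among random draws from the genes called in either. Each draw held as many genes as the gene list had members called in either. In all, 436 such percentiles were computed for pairs of lists. Of these, 5.73% lay above 97.5 and 3.67% below 2.5. If lists and genes were independent, 2.5% would lie in each by chance for a continuous measure. Many of the counts are small whole numbers, for which the chance share can differ from 2.5%. The percentiles describe the libraries and are not p-values: random genes include silent ones, and neighbouring genes that share a region are not independent. With 1 library per antibody and treatment there is no replicate error, no test between treatments and no replicate check of any difference, and the number of calls also moves with depth and enrichment.

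The 23 gene lists, the comparisons, the overlap and window settings and the rule for named genes were chosen before the data were examined. The rule named, for each comparison, up to 30 members of the osteoclast, RANK and NF-κB, immediate-early, negative regulator, macrophage, inflammatory, interferon, antigen presentation, MYC and BET lists with a peak in one list and not the other, in order of score, the 5 highest-scoring bound genes outside the lists on each side, 12 fixed genes, and the 5 highest-scoring regions of each list. Members of the other gene lists, genes in both lists of a comparison and the widest regions were chosen as examples after their values were seen. Of the 2162 list members sought, 2 had no match among protein-coding genes.

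Alternatives were the top 50% of each list by score, lists cut to the length of the shortest list of the antibody, autosomes alone, merging of regions within 500 bp, overlap over 50% of a region's own length, sharing within 1 kb, windows of 2.5 kb, placing by any overlap and random lists without matching. The widest 50% of each list and gene bodies with 5 kb on each side were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and matplotlib 3.10.9 drew the plots. The interval code was tested on simulated data: 0 of 6000 intervals differed from a direct comparison. Simulated lists of 30 genes with 3 times the background share of bound genes in the untreated BRD3 list lay above the 95th percentile in 95.5% of draws, and lists at the background share in 3.5%. These lists held independent genes and were ranked without matching. Neither pairs of lists nor genes that share a region were simulated.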

Results

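The BET proteins BRD2 and BRD3 bind acetylated histones through bromodomains, and I-BET is a small molecule that occupies those bromodomains. RANKL is the cytokine that starts osteoclast formation. The series asks how BET proteins take part in the early response of osteoclast precursors, and its ChIP-seq lists show where BRD2 and BRD3 were called in RAW264.7 cells that were untreated or had 4 h of RANKL, I-BET or both. The BRD2 lists held 578 peaks in untreated cells, 1716 with RANKL, 1067 with I-BET and 245 with RANKL and I-BET together. The BRD3 lists held 3668, 3840, 2232 and 2842 peaks in the same order. Covered length was 551 kb, 1894 kb, 1206 kb and 184 kb for BRD2 and 3563 kb, 3705 kb, 1598 kb and 1819 kb for BRD3. Each value is from 1 library, and the depth behind it is unknown.

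**Figure D1:**
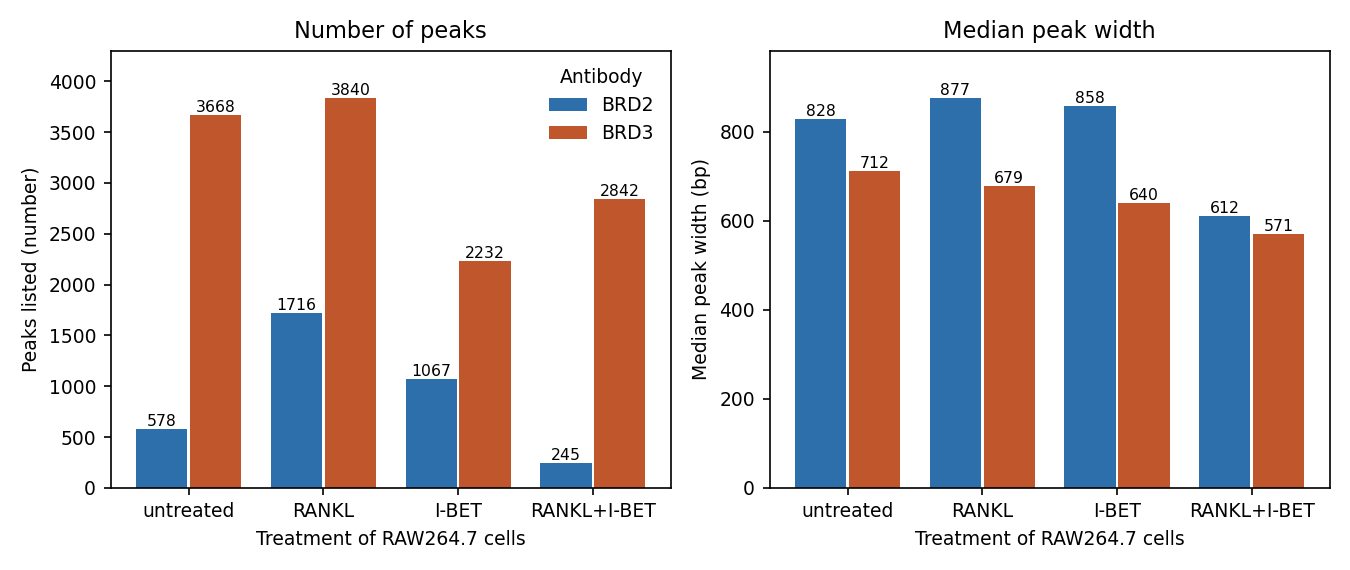
Number of peaks (left) and median peak width in bp (right) in each of the 8 peak lists, by treatment (horizontal axis) and antibody (colour), 1 library per bar. BRD2 ranges from 245 to 1716 peaks and BRD3 from 2232 to 3840, and the narrowest medians, 612 bp and 571 bp, are those of RANKL with I-BET.

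Macrophage identity genes were among the genes with a BRD3 peak under RANKL that had none in untreated cells, the comparison that asks what 4 h of the cytokine does to BET binding. Of the 35 genes on that list, 10 had a BRD3 peak in untreated cells and 14 under RANKL, with 8 in both. The 6 found under RANKL and not in untreated cells were Cd14 and Tlr2, receptors for bacterial products, the lysozyme gene Lyz2, the NADPH oxidase gene Cyba, the transcription factor gene Cebpb and the actin-bundling gene Lcp1; peaks at Cd14 and Lyz2 were 4485 bp and 3935 bp wide. That count of 6 lay at the 97.7th percentile of random draws, whose mean was 2.62. The cathepsin S gene Ctss and the lysosomal membrane gene Laptm5 had a BRD3 peak in untreated cells and none under RANKL.

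Of 30 osteoclast genes, 4 had a BRD3 peak in untreated cells and 3 under RANKL, no more than random lists, whose means were 4.50 and 4.40. Fcer1g and Tyrobp, which encode adaptors of activating receptors, were in both lists, Car2 (carbonic anhydrase) and Trem2 (an activating receptor) in the untreated list, and Ctsk, the gene of the bone-resorbing protease cathepsin K, in the RANKL list. The Ctsk region, at chromosome 3, 95496855 to 95498653, was 1799 bp wide and lay outside the gene (95499210 to 95509387), and a second RANKL region of 701 bp lay inside it. Of 32 RANK and NF-κB genes, 8 had a BRD3 peak in each list and 6 in both, with Bcl3 and Nfkb1 in the RANKL list and the kinase gene Map3k7 and its partner Tab2 in the untreated list. Among immediate-early genes, Jun, Klf4 and the phosphatase gene Dusp4 had a peak in untreated cells and Fosl2 and Jund under RANKL; among inflammatory genes, Tnf had one under RANKL and the inflammasome gene Nlrp3 in untreated cells. Nelfe, Supt4a, Phb, Mybbp1a, Cad, Lilrb4a and Ifnar1 were other listed genes with a peak under RANKL and not in untreated cells, and Mllt1, Ell, Nop58 and Irf2 had the reverse. Outside the lists, the highest-scoring genes were Cdyl2, Cyb5b, Osgepl1, Cenpn and Rfwd3 on the RANKL side and Nrf1, R3hdm2, Wdr1, Adam9 and Tm2d2 on the untreated side. Away from its ends, Lcp1 had 1 BRD3 peak inside the gene in untreated cells and under I-BET, Irf2 and Adam9 1 each under RANKL, and Adamts13 1 under I-BET. In all, 2403 of 3065 bound genes of untreated cells had a BRD3 peak under RANKL (78.4%, 95% interval 76.9% to 79.9%), 662 did not, and 601 were found under RANKL alone. Of the untreated regions, 2766 of 3668 (75.4%, 74.0% to 76.8%) overlapped a RANKL region, against 0.312% for random placements.

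With BRD2, RANKL peaks were found at 1093 genes with no BRD2 peak in untreated cells, among them NF-κB, macrophage and ribosomal protein genes. RANK and NF-κB genes numbered 2 of 32 in untreated cells (Nfkb1 and Tab1) and 9 under RANKL, where Rel, Relb, Nfkbiz, Bcl3, Map3k7, Tab2 and the kinase gene Btk joined them. Of the macrophage genes, 4 and 10 had a peak and 1, Spi1, was in both lists; Spi1 encodes the myeloid factor PU.1. Csf1r, the M-CSF receptor gene, and Cd14, Tlr2, Msr1, Cx3cr1, Ptprc, Ctss, Cyba and Lyz2 had a BRD2 peak under RANKL and not in untreated cells, and Cd68, Lyz1 and Cebpa the reverse. Genes of cytosolic ribosomal proteins, which every growing cell transcribes, numbered 22 of 84 in untreated cells and 43 under RANKL. Other listed genes on the RANKL side were Med1, Hexim1, Srm, Fosl2, Nme1, Nop58, Npm1, Oasl1, Klf6, Nelfb, Brd2, H2-DMa and Ccl9, and on the untreated side Eif4a1, Nop56, Cdk4 and Ran. The highest-scoring genes outside the lists were Vps36, Rnaseh2b, Mrps31, Fnta and Tnpo3 under RANKL and Nupl1, Mrps35, B3galt6, Sdf4 and Nifk in untreated cells.

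The RANKL counts of BRD2 came from a list of 1716 peaks set against 578, and none of these lists exceeded random draws among the genes of both lists; the 7 NF-κB genes lay at the 69.4th percentile and the 9 macrophage genes at the 50.3rd. Of the untreated BRD2 regions, 328 of 578 (56.7%, 52.6% to 60.8%) overlapped a RANKL region, and 327 of 1716 RANKL regions (19.1%, 17.2% to 21.0%) overlapped an untreated one.

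Few macrophage genes had a BRD3 peak under I-BET alone, in the comparison that asks which binding the inhibitor removes. Of the 10 macrophage identity genes with a peak in untreated cells, 1, Spi1, had a BRD3 peak under I-BET, and there its widest region was 948 bp against 4010 bp. The 9 without a call were Csf1r, Cd68, Cebpa, Ctss, the chemokine receptor gene Cx3cr1, the Fc receptor gene Fcgr3, Laptm5, Lyz1 and the scavenger receptor gene Msr1; random draws gave a mean of 3.61, and 9 lay at the 99.98th percentile. The inflammatory genes Ccl3 and Ccl4, which share 1 region, and Nlrp3 had a BRD3 peak in untreated cells and none under I-BET (97.8th percentile).

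Replication-dependent histone genes, which lie in clusters, had the highest share of any gene list with a BRD3 peak in untreated cells, 48 of 63 (76.2%, 63.8% to 86.0%). Under I-BET, 18 of the 48 had a BRD3 peak, and the 30 without one lay at the 99.99th percentile; the underlying regions numbered 27 and 8, because neighbouring histone genes share regions. Of ribosomal protein genes, 33 had a BRD3 peak in untreated cells and 16 under I-BET, with 14 in both. The 19 ribosomal protein genes without an I-BET call lay at the 98.7th percentile. Other housekeeping lists stood nearer to random draws: of 12 lysosome and V-ATPase genes 8 were in both lists, of 37 oxidative phosphorylation genes 23, and of 19 MYC network genes 10, their numbers without a call at the 29.6th, 40.2nd and 67.9th percentiles. Of 7 BET and elongation genes 6 were in both lists, Mllt1 being the exception, and Nelfcd and Supt4a had a peak under I-BET and not in untreated cells. Further listed genes with a call in untreated cells and none under I-BET were Ppan, Nfkbia, Hspd1, Hspe1, Srm, Klf4, Trem2, Tfrc, Tyrobp, Dusp4, Junb, Tab2, Map3k7 and Nop58, while Eif4e, Mybbp1a and Jund had the reverse. Among all other genes, the highest-scoring genes were Pdf, Kctd18, R3hdm2, Zmpste24 and Exosc4 on the untreated side and Ube3c, Ddx54, Rita1, Nxn and Pop1 on the I-BET side.

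Wide BRD3 regions and regions away from gene ends had a counterpart under I-BET less often. Of 3668 untreated regions, 1952 (53.2%, 51.6% to 54.8%) overlapped an I-BET region, 1197 bound genes had no I-BET call and 1868 had one. The share was 67.6% (64.4% to 70.6%) in the second width quartile (533 to 712 bp) and 36.8% (33.6% to 39.96%) in the widest (1118 to 10614 bp). It was 61.5% (59.5% to 63.5%) at gene ends and 36.9% (34.2% to 39.7%) elsewhere. The same quartiles overlapped a RANKL region in 79.6% and 72.0% of cases. Regions over 3 kb numbered 107 in untreated cells, 130 with RANKL, 0 with I-BET and 1 with both. With each BRD3 list reduced to its 2232 highest-scoring regions, a ranking with a rho of 0.167 between these lists, bound genes numbered 1875 in untreated cells and 2130 under I-BET. In those lists 5 macrophage genes and 8 histone genes had an untreated call and none under I-BET. A shortened untreated list can start with fewer called members, so these counts cannot be set against those of the full lists.

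**Figure D2:**
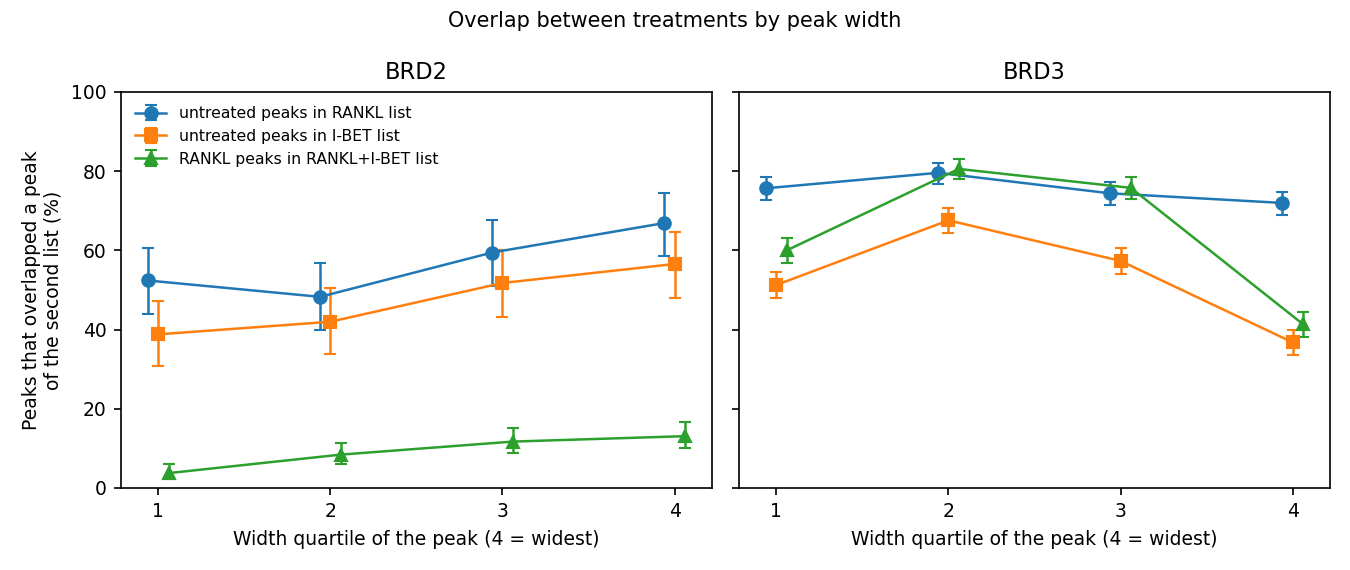
Share of peaks of one list that overlapped a peak of a second list of the same antibody (vertical axis, percent) by width quartile of the peak (horizontal axis), for BRD2 (left) and BRD3 (right). Points are single libraries and bars exact 95% binomial intervals; for BRD3 the widest quartile stands at 36.8% under I-BET and 41.4% under RANKL with I-BET, against 72.0% under RANKL alone.

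For BRD2, I-BET alone went with more called macrophage genes, 10 of 35 against 4 in untreated cells, with Spi1 and Cd68 in both. The BRD2 regions at Cd68 did not overlap, at 69665541 to 69666107 in untreated cells and 69662356 to 69664377 under I-BET on chromosome 11. Cd14, Csf1r, Ctss, the integrin gene Itgb2, Laptm5, Msr1, the NADPH oxidase gene Ncf1 and Tlr2 had a BRD2 peak under I-BET and not in untreated cells, and Cebpa and Lyz1 the reverse. These 8 lay at the 78.7th percentile of random draws. Ribosomal protein genes numbered 22 and 36, with 14 in both. Ppan, Irf2, Nfkbiz, Rel, Wdr43, Hexim1, Klf6, Lilrb4a, Brd2, H2-DMa, Hspd1 and Hspe1 were the other listed genes on the I-BET side, and Cdk4, Ccnt2, Ran and Tab1 those on the untreated side. Of genes in no list, the highest scores were at Selenok, Taf4, Ccdc66, Tep1 and Saysd1 under I-BET and at Sem1, Brpf3, Slc20a2, Smim19 and Srp19 in untreated cells. Of 578 untreated BRD2 regions, 273 (47.2%, 43.1% to 51.4%) overlapped an I-BET region and 273 of 1067 I-BET regions (25.6%, 23.0% to 28.3%) an untreated one.

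With I-BET added to RANKL, 3 of the 14 macrophage genes bound under RANKL had a BRD3 peak: Cebpa, Cebpb and Lcp1. The 11 without one were Spi1, Csf1r, Cd14, Cd68, Cx3cr1, Cyba, Fcgr3, Lyz1, Lyz2, Msr1 and Tlr2, more than in any of the 10000 random draws, whose mean was 2.99. These draws were not matched on peak width, and no width-matched draw was run for this pair of lists. RANKL regions at the 11 ran from 484 bp (Fcgr3) to 6587 bp (Spi1). Those at Cebpa, Cebpb and Lcp1 measured 590 bp, 1453 bp and 518 bp. Wider peaks at macrophage genes thus stay open as a cause here. Ctsk, Tyrobp, Tnf, Ccl3 and Ccl4 had a BRD3 peak under RANKL and none with I-BET added, as did Nfkb1, Bcl3 and the NF-κB inhibitor gene Nfkbia. Of 46 histone genes, 24 had a peak in both lists and 22 lay without one, at the 99.96th percentile. By score, lists of equal length gave 6 macrophage and 12 histone genes without a call, and the top 50% of each list 6 and 10. Shortened RANKL lists can start with fewer called members, so these counts cannot be set against those of the full lists. Of 33 ribosomal protein genes, 15 were in both lists. Of 20 MYC network genes 18 were in both lists; the 2 without a call, Phb and Ppan, lay at the 7.80th percentile, within the range of random draws, and Myc and Rrp9 had a peak with both agents and not under RANKL.

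The Myc region, chromosome 15, 61989493 to 61989914 for BRD3 and 61989509 to 61989963 for BRD2, lay inside the gene (61985341 to 61990361) near its higher-coordinate end. Myc had a peak in no other list of either antibody. Fosl2, Lilrb4a and Nelfe were further listed genes with a BRD3 peak under RANKL and none with both agents, and Relb, Nelfcd and Ell had the reverse. Of genes in no list, the highest-scoring genes were Vdac2, Cyb5b, Osgepl1, Aars and Exosc6 under RANKL and Stkld1, Surf4, Slc37a4, Tubg2 and Ints6 with both. In all, 2297 of 3004 bound genes (76.5%, 74.9% to 78.0%) had a BRD3 peak in both lists. Of the regions, 2474 of 3840 (64.4%, 62.9% to 65.9%) overlapped, 80.6% of the second width quartile and 41.4% of the widest. The narrowest quartile also fell below the second, at 38.2% against 44.3% of regions absent from untreated cells and 72.4% against 90.1% of the others.

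The BRD2 list of RANKL with I-BET was the shortest of all, and 131 of 1360 genes bound under RANKL (9.63%, 8.12% to 11.3%) had a peak in it. None of the 9 RANK and NF-κB genes was among them. Ribosomal protein genes were: 11 of 43 were in both lists, and the 32 without a call were fewer than in nearly all random draws (0.015th percentile). The mean of the draws was 41.7, but it is not an expectation for the 43. Each draw held as many genes as the ribosomal protein genes with a peak in either list, which is more than 43. Of 10 macrophage genes, Spi1 and Ctss were in both lists. Csf1r, Cd14, Msr1, Ptprc, Cx3cr1, Cyba, Tlr2, Lyz2, Tnf, Ccl9, Med1, Hexim1, Srm, Ccnt2, Fosl2, Nme1, Npm1, Oasl1, Klf6, Nelfb and Mybbp1a had a BRD2 peak under RANKL and none with both agents, and Nop56, Laptm5 and Myc had the reverse. Outside the lists the highest scores were at Vps36, Rnaseh2b, Mrps31, Fnta and Slc20a2 under RANKL and at Fastkd5, Ubox5, Ift27, Pcif1 and Nupl1 with both. Hexim1, whose product holds the elongation factor P-TEFb inactive, had a BRD2 region of 544 bp with both agents that ended at 103115283 on chromosome 11, outside the 1 kb window of the gene (103116325 to 103119725). Of the regions, 158 of 1716 (9.21%, 7.88% to 10.7%) overlapped.

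RANKL regions absent from untreated cells had a counterpart with I-BET less often than those present in untreated cells. For BRD3, 341 of 1074 regions without an untreated overlap (31.8%, 29.0% to 34.6%) overlapped a region of RANKL with I-BET, against 2133 of 2766 (77.1%, 75.5% to 78.7%) of the others. For BRD2 the shares were 5.33% (4.21% to 6.64%) and 25.7% (21.0% to 30.8%). The order held in each width quartile and in each score quartile of both antibodies. In the widest quartile of BRD3 the shares were 12.2% (8.75% to 16.4%) and 54.8% (50.9% to 58.7%). Regions near the calling threshold would drop out of several lists together, so this order can arise without any effect of I-BET. Width quartiles do not remove that. From the lowest to the highest score quartile of BRD3, regions absent from untreated cells went from 42.0% to 19.7%. The others stood at 73.5% and 76.3%. For BRD2 the values were 4.52% and 5.12%, and 26.7% and 25.8%. Dropping out near the threshold would not give the BRD3 fall if scores followed distance from the threshold. Whether they did is unknown, and no further list without I-BET was available for comparison.

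RANKL given on top of I-BET went with more BRD3 peaks at MYC network genes, 13 of 36 under I-BET and 20 with both, while bound genes of all kinds rose from 2130 to 2597. In lists of equal length by score these MYC network genes numbered 13 and 16 and all bound genes 2130 and 2089. Myc, Cad, Fbl, Hspd1, Hspe1, Rrp9, Srm and the transferrin receptor gene Tfrc had a BRD3 peak with both agents and not under I-BET, and Phb the reverse; these 8 lay at the 95.4th percentile. Cebpa, Cebpb, Lcp1, Junb and Relb were the other listed genes with a BRD3 peak with both and not under I-BET, and Spi1 had the reverse. Histone genes numbered 18 and 29, with 17 in both. Among all other genes, the highest scores were at Cklf, Adamts13, Cacfd1, Wdr5 and Rhpn1 with both agents and at Kansl1l, Rsl1d1, Aimp2, Pms2 and Elac1 under I-BET. Of 2232 I-BET regions, 2102 (94.2%, 93.1% to 95.1%) overlapped one of RANKL with I-BET.

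For BRD2 the same comparison set 1067 regions against 245, of which 154 of the first (14.4%, 12.4% to 16.7%) overlapped one of the second. Ribosomal protein genes numbered 36 and 17, with 9 in both. Macrophage genes numbered 10 and 3, and Spi1, Ctss and Laptm5 had a BRD2 peak in both lists. Nop58 and Myc had a BRD2 peak with both agents and not under I-BET. Ppan, Irf2, Nfkbiz, Eif4a1, Rel, Itgb2, Cd68, Tlr2, Wdr43, Msr1, Hexim1, Klf6, Nfkb1, Ncf1, Csf1r, Lilrb4a, Cd14, Mybbp1a, Hspd1 and Hspe1 had a peak under I-BET and none with both. Of genes in no list, the highest scores were at Selenok, Rbm39, Taf4, Stx16 and Ccdc66 under I-BET and at Ift27, Zfp961, Tmem17, Srp19 and Dhodh with both.

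**Figure D3:**
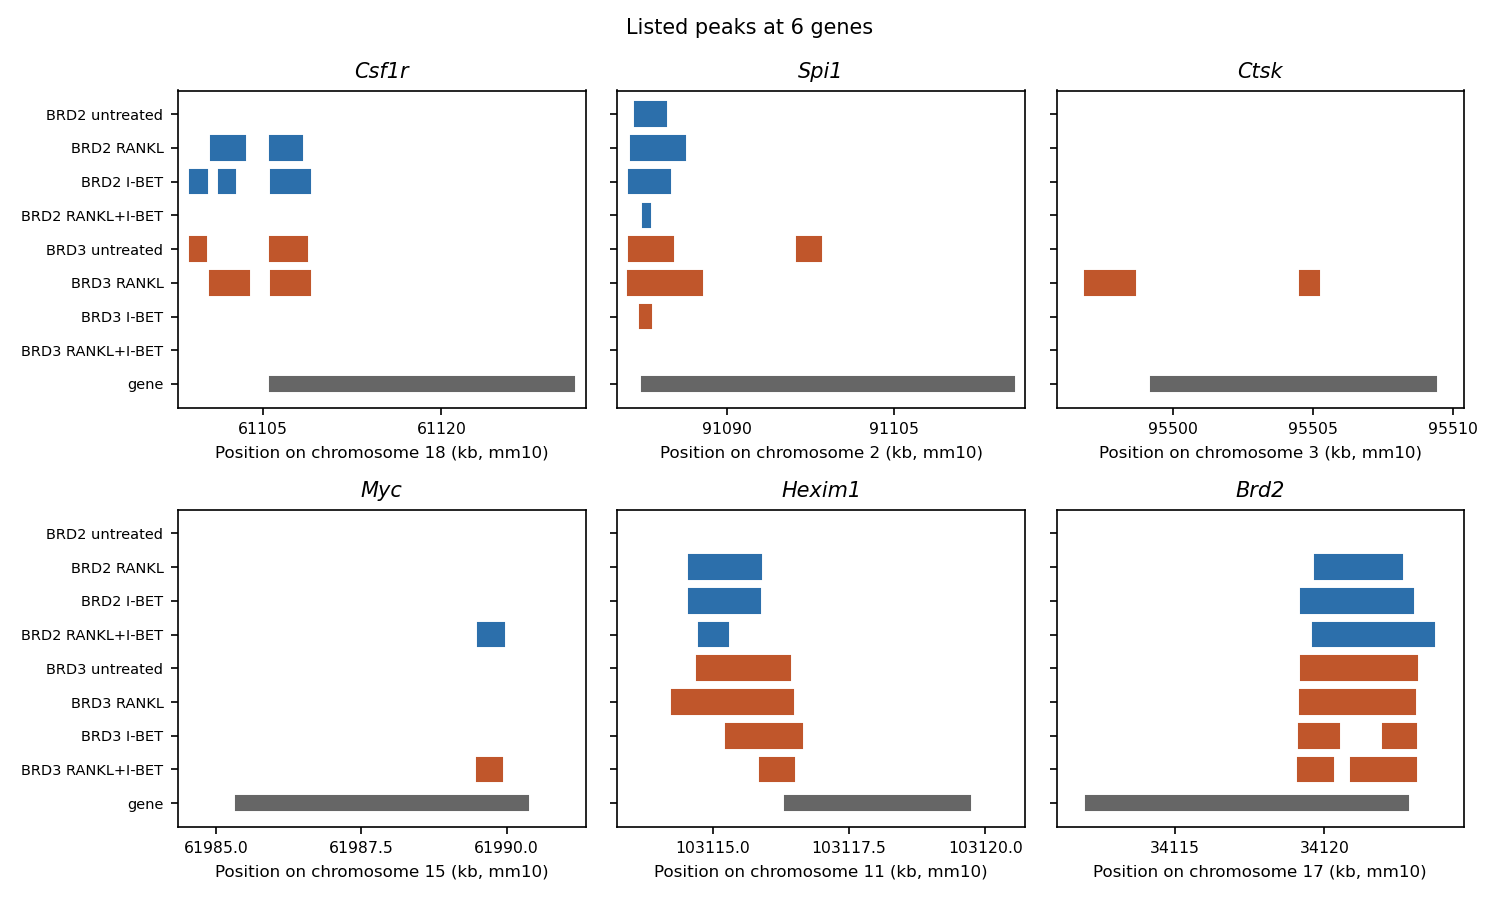
Listed peaks at Csf1r, Spi1, Ctsk, Myc, Hexim1 and Brd2, drawn to scale; the horizontal axis is the position in kb (mm10), each line of boxes is 1 peak list (BRD2 blue, BRD3 orange) and the grey box is the gene record. Csf1r has no box in either list of RANKL with I-BET, and Myc has boxes in those lists alone.

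BRD2 and BRD3 shared many genes, although the BRD2 lists were shorter. In untreated cells 254 of the 494 genes with a BRD2 peak had a BRD3 peak, where independence would give 69.2. Macrophage genes numbered 4 for BRD2 and 10 for BRD3 in untreated cells with 4 in both, 10 and 14 under RANKL with 8 in both, and 10 and 1 under I-BET with Spi1 in both. At Cd68 in untreated cells the BRD2 and BRD3 regions did not overlap. Histone genes numbered 1 for BRD2 and 48 for BRD3 in untreated cells, and 9 and 46 under RANKL. Ribosomal protein genes numbered 22 and 33 in untreated cells with 9 in both, 43 and 33 under RANKL with 18 in both, 36 and 16 under I-BET with 14 in both, and 17 and 20 under RANKL with I-BET with 7 in both. In untreated cells 1 lysosome gene, Ctsa, had a BRD2 peak, and 12 others had a BRD3 peak, among them Ctsb, Ctsd, Psap and the V-ATPase gene Atp6v1b2.

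BRD2 regions overlapped a BRD3 region of the same treatment in 315 of 578 cases in untreated cells (54.5%, 50.3% to 58.6%), 774 of 1716 under RANKL (45.1%, 42.7% to 47.5%), 215 of 1067 under I-BET (20.1%, 17.8% to 22.7%) and 74 of 245 with both (30.2%, 24.5% to 36.4%). Random placements gave 0.174% to 0.326%. Rela, Map3k14, Birc2 and Traf3 of the NF-κB pathway and Fcer1g, Fosb, Irf3, Max, Odc1 and Mllt3 had a BRD3 and no BRD2 peak at a gene end in each of the 4 treatments, while Map3k14 had 1 BRD2 peak inside the gene under I-BET. Med1 had a BRD2 and no BRD3 peak under RANKL, and Ppan, Irf2, Ctss, Nfkbiz, Eif4a1, Rel and Itgb2 under I-BET.

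Further listed genes with a BRD3 and no BRD2 peak in untreated cells were Ppan, Nfkbia, Hspd1, Hspe1, Srm, Csf1r, Klf4, Trem2, Nlrp3, Socs1, Tfrc, Tyrobp, Dusp4, Hexim1, Laptm5, Junb, Ccl3, Ccl4, Tab2 and Wdr43. Under RANKL they were Cdk4, Ppan, Phb, Nfkbia, Socs1, Pa2g4, Cebpa, Ran, Tfrc, Cd68, Ctsk, Ccl3, Ccl4, Bop1, Hspd1, Hspe1, Fbl, Junb and Lyz1. Under I-BET they were Pa2g4, Tab1, Nelfcd, Cdk4, Ran, Ccnt2, Supt4a, Ell, Jund, Ncl, Bop1, Ifnar1 and Npm1, and with both agents Npm1, Ncl, Tfrc, Ifnar1, Srm, Relb, Cad, Junb, Tab1, Lcp1, Cdk4, Hexim1, Mybbp1a, Rrp9, Hspd1, Hspe1, Pa2g4, Nelfcd, Wdr43, Mepce and Cebpa. Of genes in no list, the highest-scoring genes with a BRD2 peak alone were Brpf3, Brf2, Srp19, Pan2 and Nifk in untreated cells, Vps36, Rnaseh2b, Mrps31, Fnta and Slc20a2 under RANKL, Selenok, Rbm39, Npepl1, Stx16 and Ccdc66 under I-BET, and Fastkd5, Ubox5, Naca, Ift27 and Gm40469 with both. Those with a BRD3 peak alone were Gon4l, Nrf1, Cog8, Pdf and Galnt1, then Wdr5, Dynlrb2, Nfat5, Cdyl2 and Alg1, then Cbfb, Ccdc96, Tada2b, B9d2 and Polr2c, and Car7, Nae1, Cklf, Cog8 and Nip7 in the same order of treatments.

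**Figure D4:**
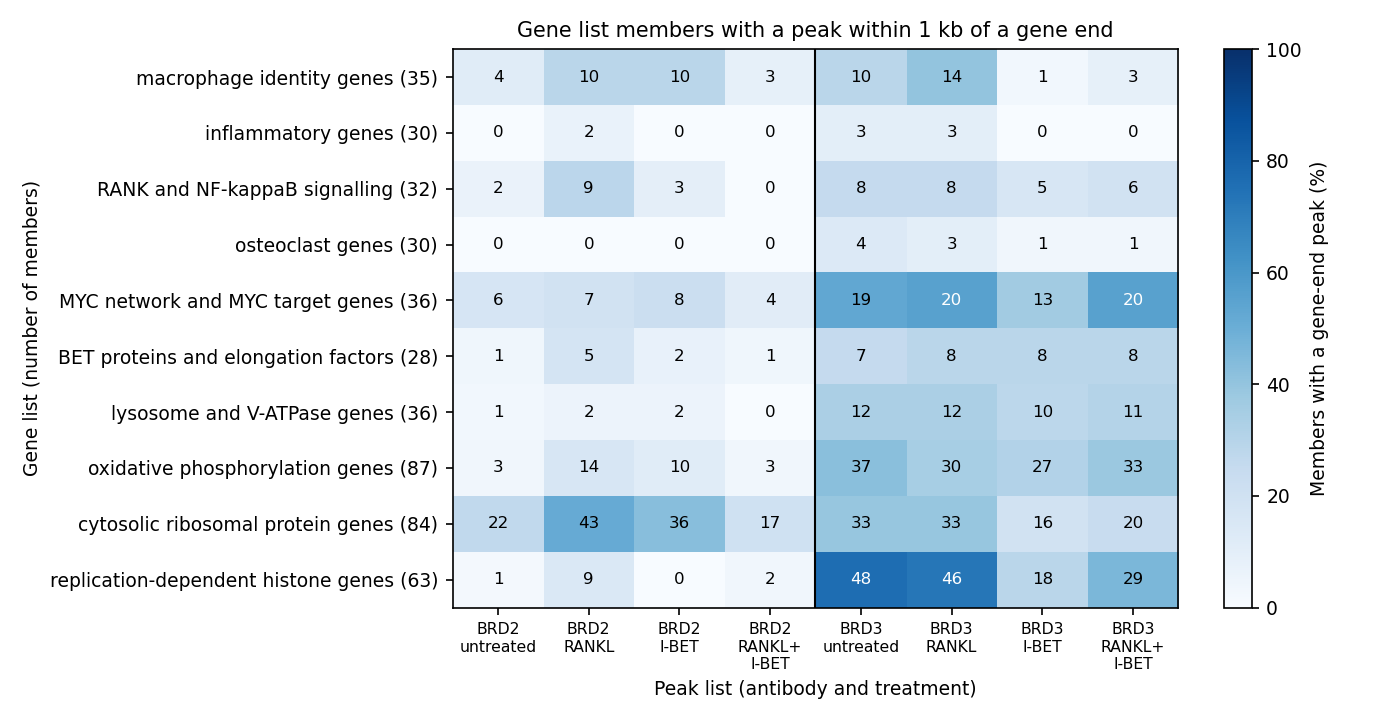
Members of 10 gene lists (vertical axis, number of members in parentheses) with a peak within 1 kb of a gene end in each of the 8 peak lists (horizontal axis). Numbers are genes and the shade is the percent of members; macrophage genes stand at 10 and 14 for BRD3 in untreated cells and RANKL and at 1 and 3 in the lists with I-BET.

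Among the genes fixed in advance, Brd2 had a peak in all lists but that of BRD2 in untreated cells. For BRD3 its untreated region measured 3902 bp, and a pair of narrower regions, of 1361 bp and 1113 bp under I-BET and of 1182 bp and 2174 bp with both agents, lay there. Hexim1 had a gene-end peak in the 4 BRD3 lists and in those of BRD2 with RANKL and with I-BET. Spi1 had one in all lists but that of BRD3 with RANKL and I-BET. Csf1r had one for BRD2 under RANKL and under I-BET and for BRD3 in untreated cells and under RANKL. Brd3 had no peak at a gene end but 1 inside the gene for BRD3 in untreated cells and under RANKL. Nfatc1 and Fos, which drive osteoclast formation, the osteoclast phosphatase gene Acp5 and the macrophage factor gene Irf8 had no peak at an end or inside the gene in any list; the lists hold only regions past the authors' threshold, so weaker binding is not excluded.

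Gene ends held most regions of both proteins. For BRD2 the share at a gene end was 68.9% (64.9% to 72.6%) in untreated cells, 61.7% (59.4% to 64.0%) under RANKL, 59.8% (56.8% to 62.8%) under I-BET and 70.6% (64.5% to 76.2%) with both. For BRD3 it was 66.3% (64.7% to 67.8%), 61.5% (59.98% to 63.1%), 76.4% (74.6% to 78.2%) and 73.7% (72.0% to 75.3%). Random placements put 3.13% to 3.22% there. BRD3 regions between genes had a median width of 1004 bp in untreated cells and 560 bp under I-BET.

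Markers of other cell types were almost without peaks. B cell, T cell and osteoblast markers had 0 in every list. Among neuron markers, Syn1 had a BRD3 peak in all 4 lists, among hepatocyte markers Apoa2 had a BRD2 peak in 3 lists, and among erythroid markers 1 gene, Tal1, had a peak in 6 lists. Of 1474 chemosensory receptor genes, 0 to 3 had a peak. Immediate-early and AP-1 genes numbered 0 to 5, antigen presentation genes 0 or 1 in every list, interferon response genes 0 to 2, negative regulators of osteoclast formation 0 to 3, heat shock genes 0 to 8 and cell cycle genes 2 to 13.

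The highest-scoring regions differed between lists. For BRD2 they lay in Kat6a in untreated cells (chromosome 8, 22859529 to 22859997, score 126), at Vps36 under RANKL (chromosome 8, 22192814 to 22193249, score 375), next to Selenok under I-BET (chromosome 14, 29967692 to 29968230, score 389) and far from any protein-coding gene with both (chromosome 8, 20122252 to 20123005, score 160). For BRD3 they lay at Dhodh in untreated cells (chromosome 8, 109608288 to 109608918, score 322), Plec under RANKL (chromosome 15, 76202188 to 76204785, score 1098), Adcy9 under I-BET (chromosome 16, 4420159 to 4420794, score 216) and Nae1 with both (chromosome 8, 104534251 to 104535042, score 1648). The next regions in order of score lay at or nearest to Nupl1, Plekha2, Sem1 and Brpf3 for BRD2 in untreated cells, Rnaseh2b, Mrps31, Fnta and Smim19 under RANKL, Rbm39, Zfp217, Cep250 and Taf4 under I-BET, and Ankrd13c, Ubox5, Naca and Rabggtb with both. For BRD3 they lay at or nearest to Gon4l, Nrf1, Pdf and Rdm1 in untreated cells, Wdr5, Olfm1 and Adcy9 under RANKL, Cbfb, Tada2b, B9d2 and Polr2c under I-BET, and Adamts13, Cklf, Nfatc3 and Cog8 with both. Across matched regions of 2 lists of an antibody, Spearman's rho of the scores was 0.0319 to 0.295 in the 8 pairs of lists, against 0.547 to 0.743 for the widths; regions are not independent replicates.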

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

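The test of fewer reads, the test on genes of nearest peak width, both tests of the BRD2 list sizes and the test of copy number were chosen only after the results were seen; the other tests in this part were chosen before.

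The values of BRD2 and BRD3 went in opposite directions under the same treatment in 7 pairs of values, and none of these differences was tested, since each value is from 1 library. From untreated cells to I-BET the number of peaks differed by 489 for BRD2 and by -1436 for BRD3. From I-BET to RANKL with I-BET it differed by -822 for BRD2 and 610 for BRD3. The share of peaks at a gene end differed by -9.05 percentage points for BRD2 and 10.1 for BRD3 from untreated cells to I-BET, and by 10.8 and -2.75 from I-BET to RANKL with I-BET. Macrophage identity genes with a peak differed by 6 for BRD2 and -9 for BRD3 from untreated cells to I-BET, and by -7 and 2 from I-BET to RANKL with I-BET. Histone genes with a peak differed by 8 for BRD2 and -2 for BRD3 from untreated cells to RANKL.

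Csf1r, Msr1, Cx3cr1 and other macrophage genes lacked a BRD3 call under I-BET, as did many wide BRD3 regions. Shortened or split wide regions would leave a call close by, but 36.8% of the widest quartile and 67.6% of the second quartile had an I-BET call within 1 kb. To the digits given, these are the shares of plain overlap reported above, so they restate that result and are no separate test. Most wide regions had no I-BET call nearby, which argues against shortening or splitting as the whole cause. Wider peaks at macrophage genes are argued against as the whole cause too: 1 of 10 kept a call, against a mean of 5.11 for random genes of the same width quartile (0.555th percentile) and of 4.50 for random genes among the 50 nearest in width (1.21st percentile). Fewer reads or weaker enrichment with I-BET cannot be told apart from loss of binding, because the lists give no signal height; among regions also called under RANKL, 47.3% of the widest and 78.5% of the second quartile had an I-BET call. A release of BRD3 by I-BET stays open as an untested hypothesis.

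The BRD2 list of RANKL with I-BET held 245 regions, among them Myc and Spi1, against 1716 under RANKL, a ratio of 7.004. The highest peak numbers named in the lists stood in a ratio of 4.63, consistent with fewer calls before the 3 peak sets were joined. Joining as the whole cause is argued against by that ratio, although it may add to the difference, since the joined regions were 26.4% and 40% of the highest peak number of set 3. Depth, enrichment and the treatment itself stay open, and the lists hold no value that separates them.

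Scores ran along the chromosome, so that Vps36, Mrps31 and Fnta on chromosome 8 all ranked high for BRD2 under RANKL. Log scores of neighbouring regions over 1 Mb apart had a median Pearson's r of 0.404 over the 8 lists, but this restates how the scores ran, and r was higher within 100 kb in all 8 lists. Values carried over between neighbours during processing cannot be told apart from other causes that reach that far, because the lists do not show how a score was made. Regional copy number of the cell line would give a region like scores in different lists, and the median Spearman's rho of matched regions was 0.164. That low value cannot decide the question, because scores changed within each list during processing would lower it too. No biological explanation other than copy number was tested. Names chosen by score may thus reflect position as well as binding.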

How the results depend on the processing

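The widest 50% of each list and the window of whole genes with 5 kb on each side were chosen only after the data were seen; the other alternatives were fixed earlier. No paired analysis was possible because each antibody and treatment has 1 library, and the unknown depth limits every count of calls. A count of 1 transcript start per gene was not run, because the gene table gives no strand, and a gene body with 5 kb upstream was replaced by 5 kb on each side. Restriction to autosomes moved none of the main list sizes, shares or locations beyond their intervals or by over 1.5 times. The same held for merging within 500 bp on list sizes and overlaps between lists, and for sharing within 1 kb on shares. Merging was not run on locations or on the fate of RANKL regions with I-BET. The direction between 2 treatments held in 40 of 40 cases for the gene-end share and 32 of 40 for bound genes. For list size it tests little, because halving each list keeps the order and no regions of a list overlapped, so lists without merging equal the main ones. Of 184 counts of gene-list members with a peak, 84 moved by over 1.5 times with the top 50% by score, 60 with lists of equal length, 56 with the widest 50%, 41 with whole genes and 5 kb on each side and 9 with the window of 2.5 kb. Random gene lists without matching on window length left 179 of 184 percentiles on the same side of the 5th and 95th percentiles, 3 passed them, 2 no longer did, and none went to the other side. This alternative tests little, because the window had the same length at every gene end.

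The top 50% by score gave 289, 858, 533 and 122 BRD2 peaks (untreated, RANKL, I-BET, both) over 263 kb, 906 kb, 605 kb and 90.2 kb, and 1834, 1920, 1116 and 1421 BRD3 peaks over 1783 kb, 1879.6 kb, 804 kb and 909.8 kb, as its construction sets. Bound genes numbered 226, 684, 405 and 108 for BRD2 and 1543, 1481, 1101 and 1340 for BRD3. Shared regions were 32.2% from untreated to RANKL, 27.3% from untreated to I-BET, 4.31% from RANKL to both and 9.19% from I-BET to both for BRD2, and 50.1%, 31.4%, 38.1% and 56.2% for BRD3. BRD2 regions shared with BRD3 were 26.3%, 22.3%, 8.82% and 13.1%. RANKL regions absent from untreated cells were shared with RANKL plus I-BET in 3.01% (BRD2) and 27.6% (BRD3), the others in 15.1% and 49.5%. Macrophage genes without a BRD3 call numbered 5 from untreated to I-BET and 6 from RANKL to both, and histone genes 10 and 10. Shorter lists hold fewer calls by construction; beyond that, the cause was not tested.

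Lists of equal length by score (245 BRD2 and 2232 BRD3 regions) gave 186, 192 and 182 bound genes for BRD2 in untreated cells, RANKL and I-BET, and 1875 and 1747 for BRD3 in untreated cells and RANKL. The direction for bound genes turned in 6 pairs here: BRD2 with 186 and 182 from untreated to I-BET, 192 and 214 from RANKL to both, and 182 and 214 from I-BET to both, and BRD3 with 1875 and 2130, 1747 and 2089, and 2130 and 2089. Shared regions were 11.8% from untreated to RANKL and 15.1% from untreated to I-BET for BRD2, and for BRD3 54.4% from untreated to RANKL, 54.7% from RANKL to both and 74.9% from I-BET to both. BRD2 regions shared with BRD3 were 33.9%, 26.5%, 22.9% and 24.5%. BRD3 RANKL regions absent from untreated cells were shared with RANKL plus I-BET in 39.7% and the others in 67.3%. Macrophage genes without a BRD3 call numbered 5 and 6, and histone genes 8 and 12, from first lists that can hold fewer called members than the full ones. Scores of matched regions had a rho of 0.0319 to 0.295 between lists, so shortening by score drops shared regions by construction and says little about shared binding; the cause of the other differences was not tested.

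Overlap over 50% of a region's own length, a stricter demand, gave shares of 6.76% from RANKL to both and 11.2% from I-BET to both for BRD2, and 71.2%, 48.9%, 58.6% and 91.7% for BRD3. BRD2 regions shared with BRD3 were 41.7% under RANKL, 15.7% under I-BET and 22.9% with both. RANKL regions absent from untreated cells were shared with RANKL plus I-BET in 3.99% (BRD2) and 27.7% (BRD3), the others in 20.6% and 72.5%.

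The widest 50% gave BRD3 shares of 57.4%, 34.0%, 43.7% and 82.4%, and BRD2 regions shared with BRD3 of 59.5% in untreated cells, 51.0% under RANKL and 16.7% under I-BET. BRD3 RANKL regions present in untreated cells were shared with RANKL plus I-BET in 52.9%. Gene-end shares were 54.3% under RANKL, 53.1% under I-BET and 62.3% with both for BRD2, and 60.4%, 55.1%, 79.6% and 79.2% for BRD3. Bound genes numbered 252, 630, 391 and 95 for BRD2 and 1489, 1430, 1140 and 1437 for BRD3, and RANKL to both turned direction for BRD3. The cause was not tested. Whole genes with 5 kb on each side turned the direction of BRD3 from untreated to RANKL, with 4139 and 4152 bound genes.

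The window of 2.5 kb, which covers more sequence, put 75.1%, 69.4%, 67.2% and 78.0% of BRD2 regions and 72.7%, 67.8%, 82.6% and 79.7% of BRD3 regions at a gene end. Placing by any overlap in place of the midpoint gave 65.9% under RANKL and 64.5% under I-BET for BRD2, and 69.5%, 64.5%, 78.6% and 75.5% for BRD3.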

Other observations

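The RNA gene classes, the named long non-coding RNAs and the widest regions below were chosen after their values were seen; the test of genes shared by BRD2 and BRD3 was prompted by the Myc calls, which had been seen, and chosen before its own result.

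Of transfer RNA genes, which RNA polymerase III transcribes, 13.7% had a BRD3 peak in untreated cells, beside 14.0% of protein-coding genes. The 2 classes were not matched on gene length, and calls at neighbouring protein-coding genes were not set apart, so the shares are not like measures. Of 408 tRNA genes, 56 had a BRD3 peak in untreated cells, 56 under RANKL, 34 under I-BET and 49 with both. For these RNA classes 20 random placements were made, with means here of 1.65, 2.90, 0.650 and 1.2. The peaks behind these counts numbered 34, 36, 24 and 32, since tRNA genes lie in groups. BRD2 peaks were at 4, 9, 3 and 1 tRNA genes, against random means of 0.15, 1, 0.75 and 0. The long non-coding, snRNA, snoRNA and miRNA classes also exceeded their random means for BRD3 in all 4 treatments.

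Of 12727 long non-coding RNA genes, 94, 248, 160 and 38 had a BRD2 peak and 518, 524, 317 and 375 a BRD3 peak in the same order. Malat1 (chromosome 19, 5795690 to 5802672) had a peak in all lists but that of BRD2 in untreated cells. Neat1 (5824708 to 5845480 on the same chromosome) had a BRD3 peak in untreated cells, of 6435 bp, and BRD2 peaks of 5661 bp under RANKL and 7939 bp under I-BET.

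The widest BRD3 regions lay in Zeb2 in untreated cells (10614 bp, chromosome 2, 45107905 to 45118518), near Rbpj under RANKL (10554 bp, chromosome 5, 53536909 to 53547462) and at Sirt4 under I-BET (2701 bp). With both agents the widest measured 6077 bp (chromosome 17, 39842890 to 39848966) and lay 101553 bp from the nearest protein-coding gene. Regions overlapping it were among the 5 widest of BRD2 in untreated cells, under I-BET and with both agents. The BRD2 list of I-BET held a region of 38569 bp on chromosome 9 (2999873 to 3038441), far from any protein-coding gene. It also held 2 regions on the mitochondrial chromosome, where no other list had a region. No filter for repeats or for regions of high background was applied here. Whether these calls far from genes and on the mitochondrial chromosome mark binding of BRD2 or BRD3 was not tested.

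Of 2403 genes with a BRD3 peak both in untreated cells and under RANKL, 666 had none under I-BET and 367 none under RANKL with I-BET. The genes absent from both numbered 304, where independence would give 101.7. For BRD2, 128 and 196 of 267 genes had none, 106 had none in either, and independence would give 94.0. Genes near the calling threshold would drop out of both lists together, so independence is not the value expected without an effect.

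Myc had a call for both proteins in the lists of RANKL with I-BET and in no other, which raised the hypothesis that both proteins gain calls at shared genes there. The test took genes called under RANKL with I-BET and not under RANKL, whatever the other lists held. Of 46 such genes for BRD2 and 55 for BRD3, among 1101 called with both antibodies in some list, 4 were shared: Rpsa, Tbc1d7, Zfp961 and Myc, which had prompted the test. Random draws gave a mean of 2.29, and 4 lay at the 86.6th percentile, so a shared gain beyond chance was not shown.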
